A study of Homo sapiens with 12 samples.

How the data were processed

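Polyadenylated RNA of the lung cancer cell lines A549 and H1650, untreated or over-expressing SRSF2, was extracted with TRIzol and sequenced by the authors, 3 libraries in each of 4 groups. Libraries were grouped by cell line and treatment as the labels give them, and replicate numbers were not used as pairs. The labels describe the control libraries as untreated, while their titles carry the letters NC, which are not explained. Whether these cells were given an empty construct is therefore not certain. Raw counts per gene were deposited as made by the authors with fastp 0.20.1, STAR 2.7.7a and featureCounts 2.0.0 on GRCh38, per the submitters' processing notes. The annotation release, the strandedness and the rule by which genes were kept in the table are not stated. The deposited FPKM values were made by the authors from the same counts. Each FPKM value equals the count times 1e+09 over the column total times a gene length, with a largest relative difference of 8.0e-13. That length equals the genomic span, introns included, for 11519 of 16139 gene IDs found in GENCODE 29 (71.4%), so FPKM was used in alternatives only.

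The count table holds 16599 genes with at least 27 counts over the 12 libraries. Every gene has a count above 0 in at least 4 A549 libraries, while 136 genes are at 0 in all H1650 libraries, so genes specific to H1650 may be under-represented. No gene of chromosome M was used here, and the level of SRSF2 was not analysed here. Symbols were taken from a gene name table (16076 IDs) or GENCODE 29 (63 IDs), and 460 IDs have none. Coordinates are from GENCODE 29 on GRCh38. Total counts ran from 23876899 to 32079027, and the 50 most abundant genes took 11.8% to 14.6% of them. No pair of replicates was a duplicate (chi-square per degree of freedom 2.29 to 8.11). Correlations of residuals between replicates of the same number ran from -0.02 to 0.024, so the numbers were not taken as pairs. In a principal component analysis of all libraries, component 1 held 89.1% of the variance and separated the lines. Component 2 (5.60%) separated SRSF2 from untreated libraries in each line, with H1650 SRSF2 replicate 3 at -33.8 against -45.2 and -42.2 for replicates 1 and 2. Within H1650, component 1 was 34.6 for replicate 3 against 45.9 and 43.1, and without this library 9719 genes were called in H1650 and 7654 for the difference.

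Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr over the 4 groups (15991 genes tested), TMM scaling, and a quasi-likelihood fit of 12 libraries with 1 mean per group and 8 residual degrees of freedom. Contrasts were SRSF2 against untreated in each line, the difference of these contrasts (A549 minus H1650), and untreated H1650 against untreated A549. p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. The overlap of calls between the lines was tested with Fisher's exact test. The common biological coefficient of variation was 0.0298 in untreated A549, 0.0342 in A549 SRSF2, 0.0338 in untreated H1650 and 0.0560 in H1650 SRSF2 libraries. A floor of 3 counts was used for ratios against a group at 0, summed over the group, and intervals of such ratios cover counting error only.

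Gene lists, 44 in all, were fixed before the data were examined, and 39 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Adjustment was over lists and both lines together, and over lists for the difference. Beside it stand the same test with an estimated correlation and the number of members called over all genes and adjusted over the list alone. The lists of mitochondrially encoded genes and of fibroblast, leukocyte, endothelial and erythroid markers had too few tested members for a test, and markers are given as CPM.

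Genes to name were chosen by a rule written before the data were examined. For each line these were the 8 genes with the largest rise and the 8 with the largest fall among those with an adjusted p under 0.05, at least 5 CPM on average in the higher group, and every SRSF2 library on the same side of every untreated library. Clone names, pseudogene-like ribosomal protein names and sex-linked marker genes were excluded. The rule added 5 genes per direction for both lines by the smaller of the fold changes, and 4 per direction for the difference and for the untreated lines. Within each list it allowed up to 4 members with the smallest adjusted p, and MFSD11. Not every gene the rule gives is named in the text.

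The pipeline was tested on simulated counts with known changes, with 15887 genes of which 200 changed in each line. At true folds of 1.25, 1.5, 2 and 4, edgeR recovered 80, 96, 96 and 100% of changed genes in A549, 70, 92, 96 and 100% in H1650 and 58, 87, 94 and 100% for the difference. False calls made up 6.5%, 3.8% and 5% of calls. Each gene was simulated with the same spread in all groups, while the real H1650 SRSF2 libraries varied most (coefficient 0.0560). Far fewer genes changed than the 32.3% called in A549 and 62.3% in H1650 in the real data. The share of false calls under those conditions was not tested. In a separate simulation of 15869 genes, a list of 44 members given a 1.25-fold change was called by camera, with 0 of 77 other list tests called. Genes were simulated as independent, so this does not test false calls of lists whose members are correlated. With the real libraries, splits that mixed SRSF2 and untreated libraries called a median of 17 lists in A549 and 11 in H1650. Such a split leaves more SRSF2 libraries in one group than in the other and keeps part of the treatment effect. These numbers are therefore not rates of false calls.

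Alternatives fixed before the data were examined were median-ratio, upper-quartile and total-count scaling, no filter and a stricter filter on low counts, a fit of each line alone, replicate number as a block, and each library left out in turn. Others were DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a filter, and camera with an estimated correlation and fry for the lists. Other splits of the libraries were tested in the same way. Tables were prepared with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.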

Results

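SRSF2 is a serine/arginine-rich (SR) splicing factor that binds exons and helps the splicing machinery select them. The effect of over-expressing it was examined in A549 and H1650, established human lung cancer cell lines. Polyadenylated RNA was sequenced from untreated cells and from cells over-expressing SRSF2, with 3 libraries in each of 4 groups. Control cells are called untreated as labelled, although the letters NC in their titles are not explained. Total counts ran from 23876899 in A549 SRSF2 replicate 1 to 32079027 in H1650 SRSF2 replicate 3. In these libraries 3 counts corresponded to 0.126 and 0.0935 CPM (counts per 1e6 counts) by plain library totals. Whether replicates were separate cultures is not stated, so p-values measure the spread between libraries that may be technical replicates. CPM values are means ± SD of 3 libraries, scaled to library totals corrected by TMM factors, except that cell type markers and the check of line mixing use plain totals. A log2 fold change compares SRSF2 with untreated cells. Its standard error (SE) was worked back as the absolute log2 fold change over the square root of the edgeR F statistic. This SE is approximate, and for large changes from few counts, as for MX1 and EGR1 in A549, it can be smaller than counting error. A value in parentheses after a gene is its log2 fold change.

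The RNA level of SRSF2 itself was not analysed here, so the over-expression stated for each library was not checked. MFSD11 (ENSG00000092931, GRCh38 chromosome 17, 76735865 to 76781449) overlaps the SRSF2 locus on the other strand. It gave 19.8 ± 0.380 CPM in untreated and 20.99 ± 0.282 CPM in SRSF2 A549 cells (log2 0.09, SE 0.07, edgeR adjusted p = 0.329). In H1650 it gave 21.4 ± 0.439 and 21.2 ± 0.970 CPM (log2 -0.02, SE 0.06, edgeR adjusted p = 0.844).

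In A549, interferon-stimulated genes rose with SRSF2 over-expression, together with immediate-early genes, p53 targets and chaperones of the endoplasmic reticulum, while DNA replication genes fell. MX1, an antiviral GTPase induced by interferon (GRCh38 chromosome 21, 41420304 to 41459214), rose from 1.61 ± 0.5001 to 39.7 ± 0.966 CPM (n = 3 per group, log2 4.62, SE 0.09). EGR1, an immediate-early transcription factor (GRCh38 chromosome 5, 138465490 to 138469315), rose from 0.835 ± 0.156 to 21.6 ± 0.557 CPM (log2 4.69, SE 0.14). E2F1, a transcription factor of the G1/S transition, fell from 103 ± 3.54 to 60.9 ± 3.74 CPM (log2 -0.75, SE 0.05). Of 15991 genes tested, 5162 (32.3%) passed an edgeR adjusted p of 0.05, 2620 higher and 2542 lower. Most changes were small: the median absolute log2 fold change of called genes was 0.28, and 280 genes rose and 60 fell by 1 or more on the log2 scale. On log2(FPKM + 1) with limma-trend these were 17 and 0, and on log2(FPKM + 0.1) 63 and 5.

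After EGR1, the largest rises in A549 by the rule for named genes included PERM1 (from 0.231 ± 0.0681 to 5.98 ± 0.153 CPM), OASL (from 0.719 ± 0.164 to 8.89 ± 0.987 CPM) and the stress-induced transcription factor ATF3 (from 5.89 ± 0.743 to 55.4 ± 3.63 CPM). CMPK2 rose from 0.880 ± 0.191 to 6.398 ± 0.611 CPM, IFI6 from 4.69 ± 0.572 to 31.6 ± 2.18 CPM and the ubiquitin-like ISG15 from 3.60 ± 0.636 to 22.7 ± 0.953 CPM. CMPK2 and RSAD2 overlap on chromosome 2 on opposite strands, and strand use in the counting is not stated, so their reads may be shared. The largest falls were in AXIN2 and RNF43, negative regulators of Wnt signalling that are themselves Wnt targets. AXIN2 went from 8.87 ± 0.715 to 3.42 ± 0.866 CPM (log2 -1.37, SE 0.16, edgeR adjusted p = 2.12e-08) and RNF43 from 7.42 ± 1.07 to 3.12 ± 0.224 CPM (log2 -1.251, SE 0.14, edgeR adjusted p = 1.23e-08). The pseudogene ZDHHC8BP (-1.24), whose reads may be shared with its parent gene, CEMIP (-1.21), LINC02593 (-1.10), RAB26 (-1.10), the water channel AQP3 (-1.04) and the epithelial transcription factor SPDEF (-0.996) followed. Their edgeR adjusted p was at most 3.57e-07. The rule asked that every SRSF2 library lie on the same side of every untreated library, which chance gives for 10% of genes with 3 against 3 libraries.

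In A549, 33 of 34 interferon response genes rose and 0 fell (the same counts adjusted over the list alone). Their median log2 fold change was 1.58 (camera adjusted p = 5.66e-108, or adjusted p = 1.44e-05 with an estimated correlation), and RIGI, a sensor of viral RNA, went from 9.38 ± 0.860 to 37.5 ± 2.01 CPM. Of the immediate-early class, 14 of 20 genes rose and 0 fell (15 and 0 adjusted over the list alone), including CCN1 (1.252) and FOSL1 (0.98) (camera adjusted p = 1.12e-28, or adjusted p = 0.00703 with an estimated correlation). Among p53 targets, 22 of 26 genes rose and 0 fell (the same counts adjusted over the list alone, camera adjusted p = 1.50e-21, or adjusted p = 1.20e-04 with an estimated correlation). They included GADD45A (1.75), BBC3 (1.33), TNFRSF10B (0.58) and MDM2 (0.71), where BBC3 encodes a pro-apoptotic BCL2-family protein and MDM2 the ubiquitin ligase of p53. For endoplasmic reticulum chaperones and related genes, 20 of 24 genes rose and 0 fell (21 and 0 adjusted over the list alone, camera adjusted p = 6.04e-22, or adjusted p = 0.00604 with an estimated correlation). HSPA5 (0.76), HERPUD1 (0.85) and HYOU1 (0.69) were among those that rose.

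NF-kB and cytokine genes rose in A549 as well: 20 of 35 genes rose and 2 fell (the same counts adjusted over the list alone, camera adjusted p = 9.61e-10, or adjusted p = 0.0182 with an estimated correlation). The best supported members were NFKB2 (0.74), BIRC3 (0.72) and RELB (0.68). In the Hippo pathway, 16 of 22 YAP/TEAD targets rose and 0 fell (the same counts adjusted over the list alone), with CCN1 and the receptor kinase AXL (0.97) among those that rose (camera adjusted p = 1.49e-20, or adjusted p = 0.0175 with an estimated correlation). In cholesterol synthesis, 14 of 25 genes rose and 1 fell (the same counts adjusted over the list alone), including HMGCS1 (0.67), INSIG1 (0.62) and MSMO1 (0.52) (camera adjusted p = 1.03e-05, or adjusted p = 0.00703 with an estimated correlation). In the amino acid response, 14 of 30 ATF4-related genes rose and 4 fell (16 and 4 adjusted over the list alone, camera adjusted p = 1.24e-10, or adjusted p = 0.00703 with an estimated correlation), with PPP1R15A (2.39), ATF3 (3.23) and STC2 (0.77) among those that rose. MAPK feedback genes respond to growth factor signalling, and 14 of 24 rose and 1 fell (15 and 1 adjusted over the list alone), with DUSP5 (0.67) and PHLDA1 (0.60) higher (camera adjusted p = 7.55e-08, or adjusted p = 0.0431 with an estimated correlation). In antigen presentation, 11 of 16 genes rose and 0 fell (the same counts adjusted over the list alone), with the class I activator NLRC5 at log2 1.248 (camera adjusted p = 5.28e-05, or adjusted p = 0.101 with an estimated correlation).

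DNA replication fell in A549, where 0 of 37 replication genes and E2F targets rose and 35 fell (the same counts adjusted over the list alone). The median was -0.29, with MCM5 (-0.46) and PCNA (-0.44) lower beside E2F1 (camera adjusted p = 3.39e-23, or adjusted p = 6.13e-04 with an estimated correlation). In mitosis, 0 of 42 G2/M genes rose and 34 fell (the same counts adjusted over the list alone), among them MKI67 (-0.40), CDC25B (-0.301) and KIF11 (-0.37) (camera adjusted p = 9.21e-12, or adjusted p = 0.148 with an estimated correlation). In homologous recombination and Fanconi anaemia repair, 0 of 34 genes rose and 22 fell (0 and 23 adjusted over the list alone), including EXO1 (-0.53) and FANCG (-0.497) (camera adjusted p = 1.42e-07, or adjusted p = 0.101 with an estimated correlation). In the oxidative stress response, 2 of 28 NRF2 targets rose and 19 fell (the same counts adjusted over the list alone), with FTL (-0.27) and GSR (-0.31) as examples (camera adjusted p = 2.44e-06, or adjusted p = 0.0697 with an estimated correlation). In drug metabolism, 0 of 17 ABC transporter and enzyme genes rose and 10 fell (1 and 10 adjusted over the list alone, camera adjusted p = 1.81e-04, or adjusted p = 0.0431 with an estimated correlation), and ALDH3A1 went from 2819 ± 42.2 to 1878 ± 87.5 CPM.

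In the heat shock response of A549, 1 of 20 genes rose and 15 fell (1 and 16 adjusted over the list alone), with AHSA1 at log2 -0.34 (camera adjusted p = 1.03e-06, or adjusted p = 0.101 with an estimated correlation). In Wnt signalling, 3 of 13 targets rose and 8 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0112, or adjusted p = 0.105 with an estimated correlation). BMP4 (-0.79) was lower beside AXIN2 and RNF43, and the adhesion receptor CD44 (0.36) was higher. In all, 27 of 39 lists were called, 20 higher and 7 lower, and 11 of these also with an estimated correlation. Splits of the same 6 libraries that mixed the groups, and so keep part of the treatment effect, called up to 19 lists.

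**Figure D1:**
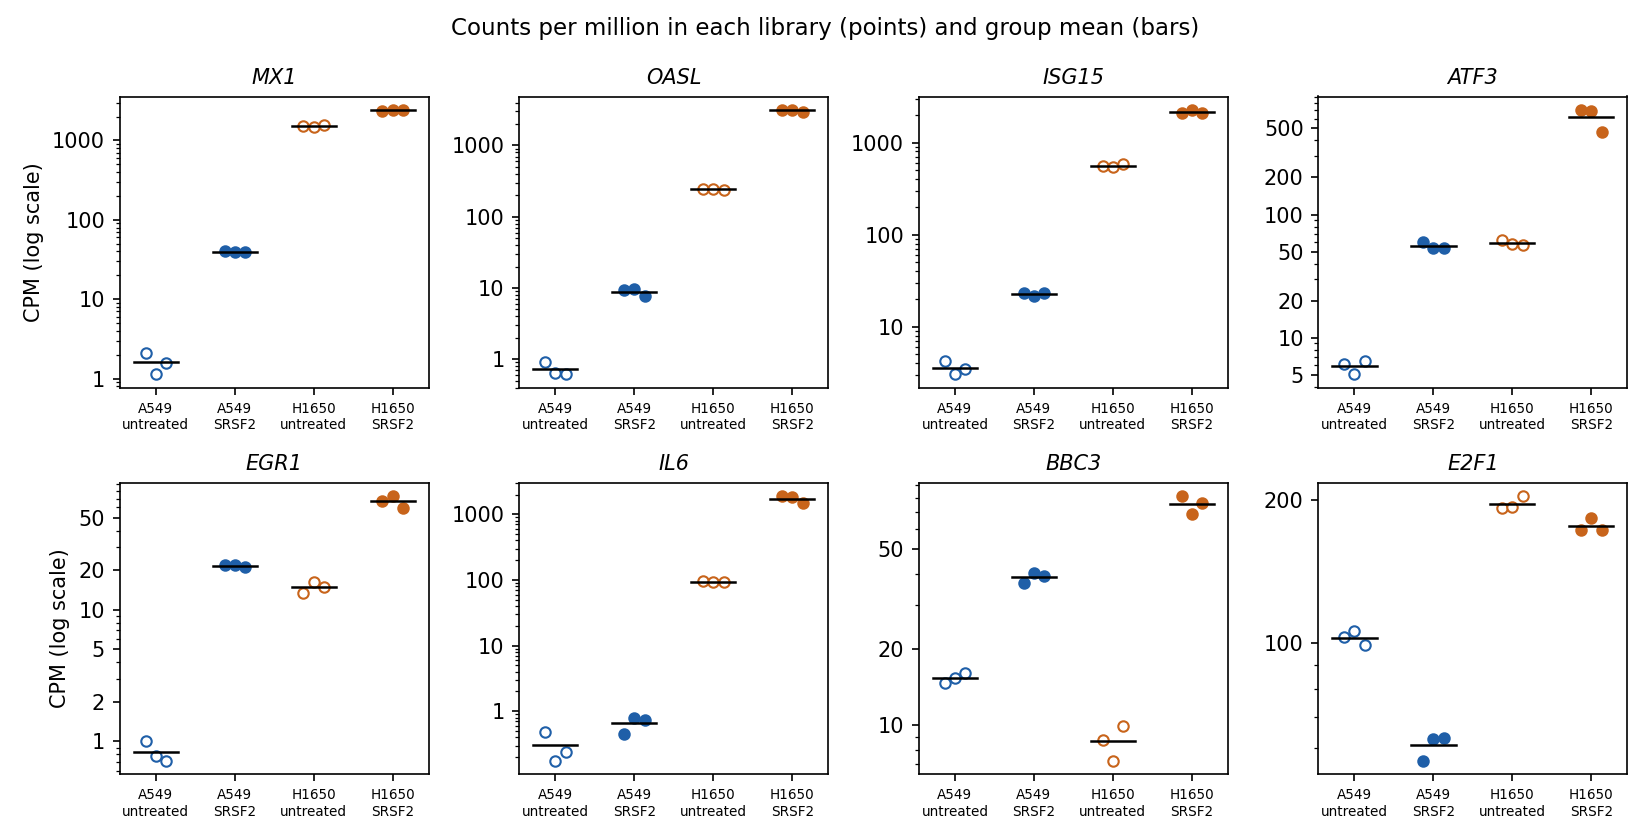
CPM on a log axis for 8 genes in the 12 libraries, with 1 point per library (open, untreated; filled, SRSF2; blue, A549; orange, H1650) and a bar at the mean of each group of 3. MX1 went from 1.61 ± 0.5001 to 39.7 ± 0.966 CPM in A549 and IL6 from 94.1 ± 0.944 to 1735 ± 219.5 CPM in H1650.

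Interferon-stimulated genes, cytokine genes, immediate-early genes and class I antigen presentation genes were higher in SRSF2 over-expressing than in untreated H1650 cells. IL6, a cytokine under NF-kB control (GRCh38 chromosome 7, 22725884 to 22732002), rose from 94.1 ± 0.944 to 1735 ± 219.5 CPM (n = 3 per group, log2 4.20, SE 0.06). RSAD2, an antiviral enzyme induced by interferon (GRCh38 chromosome 2, 6865806 to 6898239), rose from 65.4 ± 3.37 to 1666 ± 162 CPM (log2 4.67, SE 0.06). CENPF, a kinetochore protein, fell from 214 ± 19.2 to 89.4 ± 4.08 CPM (log2 -1.26, SE 0.05). In this line 9957 of 15991 genes (62.3%) passed an edgeR adjusted p of 0.05, 4954 higher and 5003 lower. The median absolute log2 fold change of called genes was 0.48, and 1163 genes rose and 535 fell by 1 or more on the log2 scale. On log2(FPKM + 1) with limma-trend these were 192 and 31, and on log2(FPKM + 0.1) 345 and 143.

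By the rule for named genes, the largest rise in H1650 was in CNN1, an actin-binding protein of smooth muscle, from 0.569 ± 0.181 to 21.4 ± 5.40 CPM (log2 5.21, SE 0.20). The fatty acid hydroxylase FA2H went from 2.22 ± 0.577 to 61.9 ± 4.36 CPM, the activity-regulated gene ARC from 1.36 ± 0.174 to 35.7 ± 11.1 CPM and the YAP target ANKRD1 from 4.52 ± 0.290 to 95.2 ± 22.8 CPM. The keratin KRT34 rose from 0.580 ± 0.0967 to 11.9 ± 1.34 CPM, the linker histone H1-4 from 0.495 ± 0.256 to 9.97 ± 3.67 CPM and the growth factor IGF2 from 0.507 ± 0.203 to 9.46 ± 0.297 CPM. In H1650 SRSF2 replicate 3, CNN1, ARC, ANKRD1 and H1-4 were lower than in replicates 1 and 2, with ARC at 23.3 against 38.9 and 44.8 CPM and H1-4 at 5.74 against 12.3 and 11.9 CPM. The largest falls were in APBA1 (from 17.4 ± 0.554 to 3.49 ± 0.389 CPM) and SLITRK6 (from 22.7 ± 1.44 to 4.53 ± 0.473 CPM). LMO1 (-2.28), ARHGEF19 (-2.25), ST8SIA1 (-2.10), the immune checkpoint ligand VTCN1 (-2.03), PRRT4 (-1.98) and ZNF608 (-1.87) followed. The edgeR adjusted p of these genes, RSAD2 included, was at most 4.38e-12.

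In H1650, 33 of 34 interferon response genes rose and 1 fell (the same counts adjusted over the list alone). The median was 0.94, with OASL (3.68), ISG20 (3.68) and HERC5 (2.76) after RSAD2 (camera adjusted p = 2.46e-69, or adjusted p = 6.51e-05 with an estimated correlation). Among NF-kB and cytokine genes, 28 of 35 members rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 7.63e-23, or adjusted p = 0.00293 with an estimated correlation). Their median was 1.30, and IL6 (4.20), SOD2 (2.21) and TNFAIP3 (2.87) had the smallest adjusted p. Of the immediate-early class, 19 of 20 genes rose and 1 fell (the same counts adjusted over the list alone), with KLF4 (2.99), KLF10 (2.27) and ATF3 (3.40) higher (camera adjusted p = 8.38e-33, or adjusted p = 0.00703 with an estimated correlation). In antigen presentation, 15 of 16 genes rose and 0 fell (the same counts adjusted over the list alone, camera adjusted p = 2.70e-14, or adjusted p = 0.0145 with an estimated correlation). B2M, the light chain of class I molecules, went from 1209 ± 21.8 to 3341 ± 42.1 CPM, and HLA-B (1.57) and HLA-E (1.44) rose too, though class I genes share sequence and reads may be split between them. In the list of endoplasmic reticulum chaperones and related genes, 20 of 24 genes rose and 2 fell (20 and 3 adjusted over the list alone, camera adjusted p = 3.47e-13, or adjusted p = 0.0152 with an estimated correlation). HSPA5 (1.46), DNAJB9 (2.92) and the transcription factor XBP1 (2.40) were among those that rose.

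Genes on both sides of apoptosis rose in H1650. Of the pro-apoptotic side, 14 of 24 genes rose and 6 fell (the same counts adjusted over the list alone, camera adjusted p = 1.33e-04, or adjusted p = 0.0125 with an estimated correlation). The BH3-only genes PMAIP1 (from 34.0 ± 0.821 to 403 ± 43.4 CPM) and BBC3 (from 8.63 ± 1.37 to 75.7 ± 6.07 CPM) were among those that rose. Of the anti-apoptotic side, 6 of 10 genes rose and 2 fell (the same counts adjusted over the list alone), with BIRC3 (2.29) and MCL1 (1.13) among those that rose (camera adjusted p = 9.15e-04, or adjusted p = 0.0854 with an estimated correlation). Among p53 targets, 15 of 26 genes rose and 5 fell (16 and 5 adjusted over the list alone), with GADD45A (2.82) and AEN (1.55) beside BBC3 (camera adjusted p = 1.86e-05, or adjusted p = 0.00703 with an estimated correlation). Their median was 0.36 from fitted values and 0.42 with the 1 member left out that had a group at 0 and no more than the floor in the other. In MAPK feedback, 18 of 24 genes rose and 3 fell (the same counts adjusted over the list alone), with EPHA2 (1.68), FOSL1 (2.15) and DUSP4 (1.47) higher (camera adjusted p = 4.89e-11, or adjusted p = 0.0175 with an estimated correlation).

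Most replication-dependent histone transcripts end in a stem-loop rather than a poly(A) tail. In H1650, 17 of 18 histone genes rose and 0 fell (the same counts adjusted over the list alone), with a median of 1.61 (camera adjusted p = 2.49e-08, or adjusted p = 0.138 with an estimated correlation). Reads of H2AC6 (1.84), H2BC21 (1.81) and H2BC5 (1.92) may be shared with near-identical copies. In A549, 9 of 18 histone genes rose and 0 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0117, or adjusted p = 0.471 with an estimated correlation). In mitosis, 2 of 42 G2/M genes rose and 32 fell (the same counts adjusted over the list alone) in H1650, with PLK1 (-0.94) and TOP2A (-1.18) beside CENPF (camera adjusted p = 1.42e-08, or adjusted p = 0.215 with an estimated correlation). DNA replication went both ways: 11 of 37 genes rose and 15 fell (the same counts adjusted over the list alone), with ORC6 (0.85) and CDC6 (0.63) higher, and the list was not called (camera adjusted p = 0.326). In Wnt signalling, 7 of 13 targets rose and 2 fell (the same counts adjusted over the list alone), with MYC (1.09) and CCND1 (0.82) among those that rose (camera adjusted p = 0.0145, or adjusted p = 0.126 with an estimated correlation).

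In the oxidative stress response of H1650, 5 of 28 NRF2 targets rose and 19 fell (the same counts adjusted over the list alone), with TKT at log2 -0.80 (camera adjusted p = 0.00689, or adjusted p = 0.215 with an estimated correlation). In recombination and Fanconi repair, 2 of 34 genes rose and 22 fell (the same counts adjusted over the list alone), as for NBN (-0.54) and EXO1 (-0.66) (camera adjusted p = 0.0146, or adjusted p = 0.402 with an estimated correlation). In the amino acid response, 16 of 30 ATF4-related genes rose and 11 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0146, or adjusted p = 0.148 with an estimated correlation). WARS1 (from 107 ± 2.45 to 611 ± 12.8 CPM) and PPP1R15A (from 87.7 ± 4.44 to 844 ± 148 CPM) were among those that rose. In all, 21 of 39 lists were called, 18 higher and 3 lower, and 8 of these also with an estimated correlation. Splits of the same 6 libraries that mixed the groups, and so keep part of the treatment effect, called up to 14 lists.

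**Figure D2:**
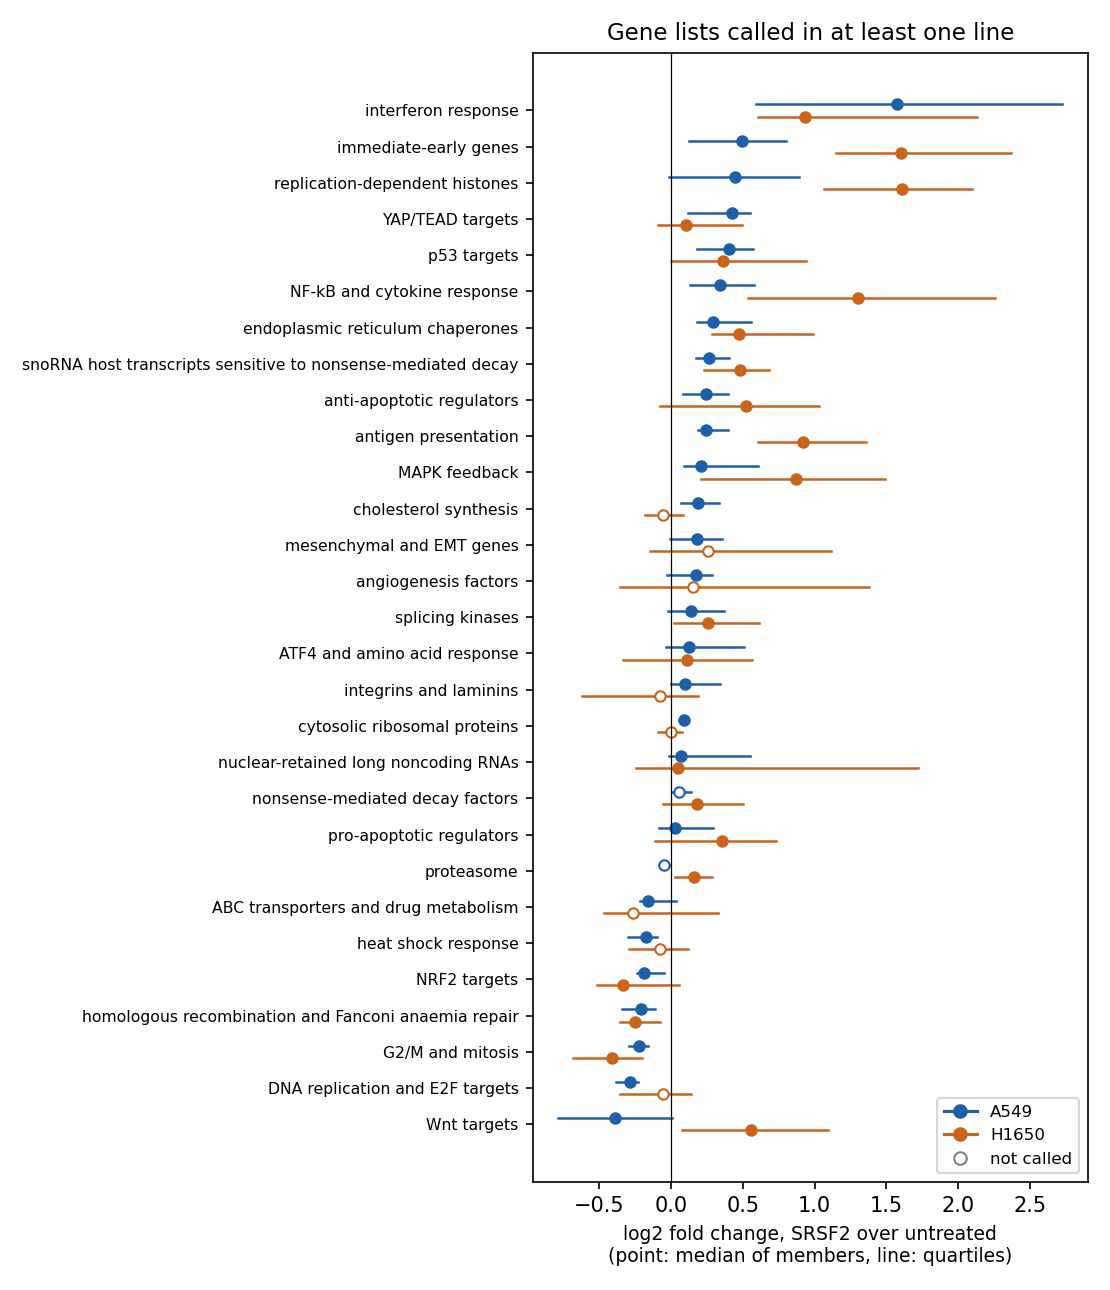
Median log2 fold change (points, with lines from the lower to the upper quartile of members) of each list called in at least 1 line, in A549 (blue) and H1650 (orange), with open points where the list was not called. Interferon response genes had medians of 1.58 in A549 and 0.94 in H1650, and Wnt targets of -0.39 and 0.56.

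No list of splicing machinery genes was called by camera in either line, while fry, which tests each list by itself, called hnRNP proteins (fry adjusted p = 0.00302) and the core spliceosome (fry adjusted p = 0.00803) in H1650. Of the SR protein genes other than SRSF2, 1 of 12 genes rose and 2 fell (the same counts adjusted over the list alone) in A549 and 4 of 12 genes rose and 4 fell (the same counts adjusted over the list alone) in H1650, with camera adjusted p = 0.484 in A549 and 0.765 in H1650. In H1650 SRSF1 (log2 -0.41, SE 0.04) and SRSF6 (-0.31, SE 0.04) fell, and SRSF3 (0.25, SE 0.04) and TRA2B (0.28, SE 0.04) rose. Among hnRNP proteins, 4 of 23 genes rose and 3 fell (the same counts adjusted over the list alone) in A549 and 6 of 23 genes rose and 11 fell (6 and 12 adjusted over the list alone) in H1650, with camera adjusted p = 0.992 in A549 and 0.350 in H1650. In the core spliceosome, 6 of 44 genes rose and 10 fell (the same counts adjusted over the list alone) in A549 and 23 of 44 genes rose and 10 fell (23 and 12 adjusted over the list alone) in H1650, with camera adjusted p = 0.193 in A549 and 0.541 in H1650. Epithelial genes (0.113 in A549 and 0.974 in H1650), TGF-beta response genes (0.436 in A549 and 0.452 in H1650), glycolysis and hypoxia genes (0.508 in A549 and 0.851 in H1650) and lung epithelial lineage genes (0.900 in A549 and 0.224 in H1650) were not called by camera either. The same held for MYC targets and ribosome biogenesis (0.660 in A549 and 0.2998 in H1650), oxidative phosphorylation (0.0860 in A549 and 0.250 in H1650) and matrix proteases (0.182 in A549 and 0.391 in H1650).

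Several of the strongest responses were shared by the lines. OASL rose by log2 3.63, SE 0.13 in A549 and 3.68, SE 0.04 in H1650, ATF3 by 3.23, SE 0.13 and 3.40, SE 0.09, and CMPK2 by 2.85, SE 0.15 and 2.39, SE 0.05. PPP1R15A, a regulator of the translation stress response, rose by log2 2.39, SE 0.08 in A549 and 3.27, SE 0.08 in H1650, and EGR1 by 4.69 and 2.16. Among genes lower in both lines, the receptor NOTCH3 went from 141 ± 6.86 to 79.5 ± 10.3 CPM in A549 and from 193 ± 5.50 to 109 ± 8.03 CPM in H1650 (log2 -0.83 and -0.83). The sphingosine phosphate receptor S1PR5 (-0.96 and -0.97), the ligand WNT5A (-0.87 and -0.93), DPYSL5 (-0.79 and -1.05) and MXD3 (-0.79 and -0.83) also fell in A549 and H1650.

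Of 3853 genes called in both lines, 2898 (75.2%) had the same sign and 955 the opposite one. Genes higher in both numbered 1509, against 811.7 for independent calls (odds ratio 3.91, Fisher's exact test, p = 1.24e-211). Genes lower in both numbered 1389, against 795.3 (odds ratio 3.28, Fisher's exact test, p = 7.84e-158). Genes higher in A549 and lower in H1650 numbered 501, against 819.7, and the reverse 454, against 787.5. Fisher's test treats genes as independent, which they are not, so its p-values do not measure replication of the overlap. Across 15991 genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.243 and a Spearman correlation of 0.253. By 1 or more on the log2 scale, 113 genes rose and 6 fell in both lines, against 20.4 and 2 for independent calls.

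**Figure D3:**
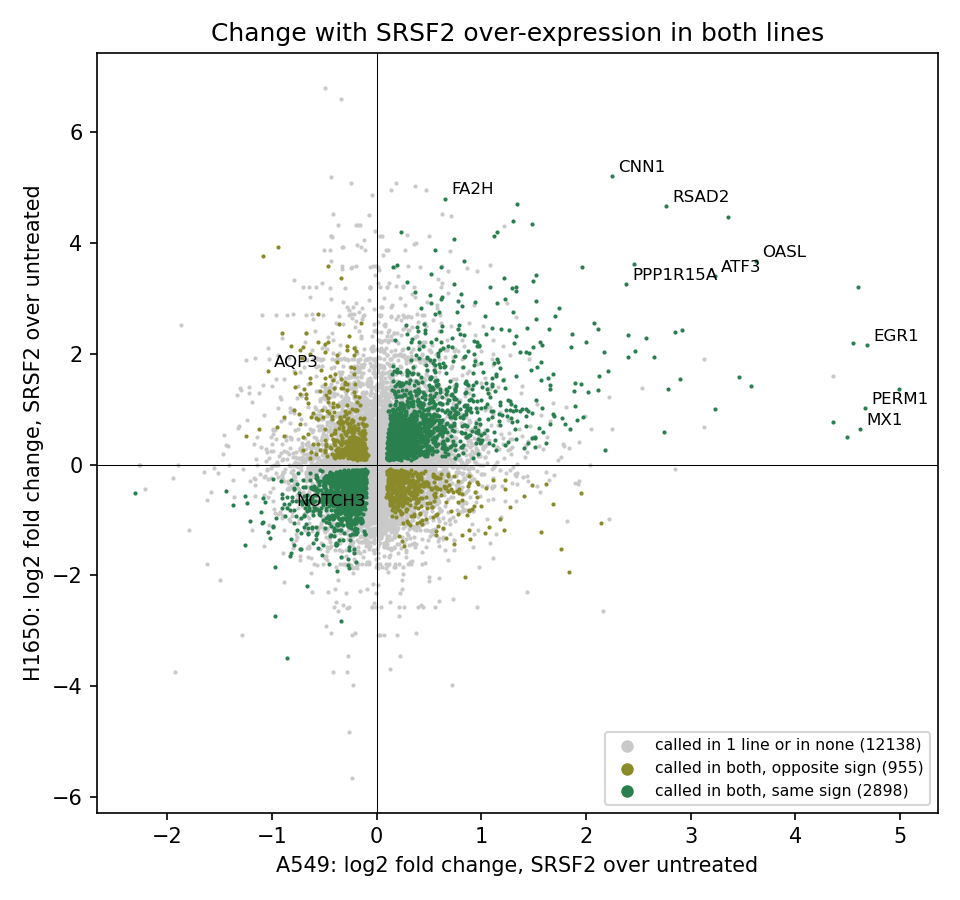
Log2 fold change of SRSF2 over untreated cells in A549 (x axis) and H1650 (y axis) for 15991 genes, 1 point per gene. Of the genes called in both lines, 2898 changed the same way (green) and 955 in opposite ways (olive).

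The size of the response differed between the lines for many genes, in a test of the difference itself (A549 minus H1650). MX1 rose by 3.97 more on the log2 scale in A549 (SE 0.10), where its untreated level was 1.61 ± 0.5001 CPM against 1522 ± 40.1 CPM in H1650. PERM1 (difference 3.64, SE 0.31) also rose more in A549. UCN2 (3.77, SE 0.75) rose from 4.38 ± 0.816 to 15.6 ± 0.819 CPM in A549 and had at most 0.199 CPM in H1650 on average, while IGF2 (-4.23, SE 0.28) rose more in H1650. At edgeR adjusted p under 0.05, 7601 of 15991 genes differed, 3843 with a more positive change in A549 and 3758 with a more positive change in H1650.

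IFI44L, an interferon-induced gene, had 3 counts over the 3 untreated and 69 over the 3 SRSF2 A549 libraries, a ratio of 25.1 (95% interval 8.25 to 125, counting error only). Its difference was called (edgeR adjusted p = 1.78e-08) but was negative on log2(FPKM + 1) and log2(FPKM + 0.1) scales, which shrink changes at low values. LIN7A, TPPP3 and SOX8 rose in H1650 from levels at or near 0. LIN7A went from 0 to 12 counts over 3 libraries, at least 4.18-fold higher, and TPPP3 from 0 to 8, at least 2.79-fold higher, against a floor of 3 counts over the group. SOX8 went from 2 to 33 counts, a ratio of 17.3 (95% interval 4.41 to 148).

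Cytokine and immediate-early genes rose more in H1650 than in A549. The NF-kB and cytokine list had a median difference of -1.10 (camera adjusted p = 1.49e-14, or adjusted p = 0.0405 with an estimated correlation), with 2 of 35 members more positive in A549 and 24 in H1650 (the same counts adjusted over the list alone). For the other lists, the median difference is followed by the camera adjusted p with the preset and with an estimated correlation. The changes were more positive in H1650 for immediate-early genes (-0.95, 5.99e-14 and 0.0754), MAPK feedback (-0.74, 1.26e-06 and 0.0754), antigen presentation (-0.55, 4.30e-06 and 0.0913), Wnt targets (-0.80, 1.89e-04 and 0.0754) and histones (-1.23, 2.96e-04 and 0.466). The same direction was called for endoplasmic reticulum chaperones (-0.21, 0.00157 and 0.327), pro-apoptotic regulators (-0.37, 0.00261 and 0.0754) and anti-apoptotic regulators (-0.42, 0.0492 and 0.395). The call for anti-apoptotic regulators was lost with upper-quartile and total-count scaling and with several single libraries left out. DNA replication genes fell more in A549 (-0.23, 4.22e-04 and 0.0754), and cholesterol synthesis (0.26, 0.0125 and 0.0754) and G2/M genes (0.21, 0.00261 and 0.707) changed more positively in A549. The interferon list did not differ as a whole (camera adjusted p = 0.902), with 18 members more positive in A549 and 13 in H1650 (the same counts adjusted over the list alone). Of the 14 lists called for a difference, 1 was also called with an estimated correlation. Other splits of the libraries often called as many lists, but they keep part of the treatment effect and do not measure chance.

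The untreated lines differed in most genes, which gives the background for the comparisons above. The cadherin CDH3 was at 0.432 ± 0.257 CPM in A549 and 1529 ± 38.5 CPM in H1650 (log2 11.79, SE 0.09, H1650 over A549), and the protease ST14 (log2 10.91, SE 0.10) was higher in H1650 too. So was IFI44L, with 13399 counts over 3 libraries against 3 in A549 (ratio 4109, 95% interval 1406 to 19930), and ISG15 stood at 559 ± 21.3 against 3.60 ± 0.636 CPM. The glutathione transferase GSTP1 had 52330 counts in untreated A549 and 1 in H1650 (ratio 56880, 95% interval 10210 to 2247000), and the aldehyde dehydrogenase ALDH3A1 stood at 2819 ± 42.2 against 0.165 ± 0.00346 CPM. TCIM was at least 3747-fold and TBX18 at least 2903-fold higher in A549, with 0 counts over the 3 untreated H1650 libraries. In all, 13182 of 15991 genes (82.4%) differed at edgeR adjusted p under 0.05, 6411 higher in H1650 and 6771 lower.

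Markers of other cell types were low but not all absent. The fibroblast collagen gene COL1A1 was at 11.6 to 14.6 CPM in untreated and 7.999 to 9.80 CPM in SRSF2 A549 libraries (edgeR adjusted p = 3.89e-04). In H1650 it was at 9.52 to 10.7 and 4.74 to 7.20 CPM (edgeR adjusted p = 6.89e-05). COL3A1 was at 0.438 to 0.783 CPM in A549 (edgeR adjusted p = 0.729), and at 11.026 to 13.1 and 12.8 to 14.4 CPM in untreated and SRSF2 H1650 libraries (edgeR adjusted p = 0.0196). The monocyte marker CD14 fell in A549, with 5.51 to 6.58 CPM in untreated and 3.56 to 4.08 CPM in SRSF2 libraries (edgeR adjusted p = 0.00235) and ran to 0.597 CPM in H1650 (edgeR adjusted p = 0.491). In H1650 the endothelial marker ESAM rose, with 2.63 to 3.43 CPM in untreated and 4.46 to 5.48 CPM in SRSF2 libraries (edgeR adjusted p = 3.93e-05) and so did the erythroid gene HBG2, with 0.129 to 0.168 and 0.374 to 0.485 CPM (edgeR adjusted p = 0.00616). In A549 they ran to 3.60 and 0.363 CPM (edgeR adjusted p = 0.164 and 0.567). The B cell marker CD79A ran to 0.641 CPM in the highest library (edgeR adjusted p = 0.404 in A549 and 0.310 in H1650). The leukocyte marker NKG7 was at 0.105 to 0.401 CPM in untreated and 0.04 to 0.084 CPM in SRSF2 A549 libraries. In H1650 NKG7 was at 0.161 to 0.362 and 0.106 to 0.125 CPM, with SRSF2 libraries of each line at or near the floor of 3 counts. CLDN5 ran to 0.665 CPM and COL6A3 to 0.403 CPM in the highest library. Mixing of the lines was checked with genes at 20 or more CPM in every untreated library of one line and under 0.2 CPM in every untreated library of the other. The 75 A549 marker genes summed to 0.0404% to 0.0427% of their A549 level in untreated H1650 libraries and to 0.0758% to 0.0804% in H1650 SRSF2 libraries. The 3 H1650 marker genes summed to 0.0765% to 0.143% of their H1650 level in untreated A549 and to 1.10% to 1.36% in A549 SRSF2 libraries. In untreated and SRSF2 A549 cells, these were at 0.0358 and 0.890 CPM for the interferon-induced gene IFI44L, 0.0724 and 2.41 CPM for a gene without a symbol here (ENSG00000117289) and 0.179 and 0.224 CPM for PLXDC2. Their untreated H1650 levels were 147, 25.8 and 109 CPM.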

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

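The tests of carry-over, of library scaling and of spread between replicates in this part were chosen after the results were seen. The genes and lists in this paragraph and the next stood out because their change differed between the lines. The difference was tested directly and is given as A549 minus H1650 on the log2 scale. Genes that rose in both lines, and more in H1650, were CNN1 (-2.96), FA2H (-4.15), ARC (-3.37), RSAD2 (-1.91), ANKRD1 (-3.09), KRT34 (-2.86), PPP1R15A (-0.88), RIGI (-0.22), FOSL1 (-1.17), GADD45A (-1.08), BBC3 (-1.80), MDM2 (-0.54), HSPA5 (-0.70), HYOU1 (-0.23), DNAJB9 (-1.77), BIRC3 (-1.57), TNFAIP3 (-2.05), HMGCS1 (-0.66), CD44 (-0.17), HLA-E (-1.09), B2M (-1.250), HLA-B (-1.05), KLF4 (-2.37), KLF10 (-1.70), IL6 (-3.06), SOD2 (-1.81), ISG20 (-2.84), HERC5 (-1.99), H2AC6 (-1.21), H2BC21 (-1.249), H2BC5 (-1.44), PMAIP1 (-2.95), AEN (-1.04), EPHA2 (-1.37), DUSP4 (-1.27), CLK1 (-0.61), SRPK2 (-0.72), SNHG1 (-0.73), SNHG15 (-0.72), LINC-PINT (-1.12), MYC (-0.80), MCL1 (-0.81) and WARS1 (-2.24). Genes that rose in both lines, and more in A549, were EGR1 (2.53), PERM1 (3.64), MX1 (3.97), CMPK2 (0.46), IFI6 (2.17), ISG15 (0.70), IFI44L (3.99), CCN1 (0.85), STC2 (0.61), AXL (0.35), NLRC5 (0.37), GAS5 (0.20) and DUSP5 (0.36). Genes called lower in H1650 and not called in A549 were APBA1 (2.55), SLITRK6 (2.31), LMO1 (2.12), ARHGEF19 (2.16), ST8SIA1 (2.60), PRRT4 (2.23), ZNF608 (1.69), SRSF1 (0.40), SRSF6 (0.31) and NBN (0.62). Genes that fell in A549 and rose in H1650 were RNF43 (-1.77), AQP3 (-2.73), SOX8 (-4.88), FTL (-0.56), AHSA1 (-0.495), CCND1 (-0.95), CDC6 (-0.81), ORC6 (-1.01) and PSMC4 (-0.83). Genes called higher in H1650 and not called in A549 were H1-4 (-3.10), IGF2 (-4.23), XBP1 (-2.30), SRSF3 (-0.26), TRA2B (-0.36), UPF3B (-1.48), PNRC2 (-0.86), NEAT1 (-1.71) and PSMC1 (-0.56). Genes that fell in both lines, and more in H1650, were MKI67 (0.28), KIF11 (0.31), GSR (0.36), CENPF (1.06), PLK1 (0.66), TOP2A (0.96) and TKT (0.66). Genes that fell in both lines, and more in A549, were ZDHHC8BP (-0.53), E2F1 (-0.60), MCM5 (-0.27) and FANCG (-0.22). Genes that rose in A549 and fell in H1650 were VTCN1 (2.87), UCN2 (3.77), INSIG1 (1.16) and ITGA3 (0.58). Genes called higher in A549 and not called in H1650 were MSMO1 (0.495) and PVT1 (0.49). Called lower in A549 and not called in H1650 was SPDEF (-1.37). For IFI44L, SOX8 and UCN2 the fitted values depend on the prior count, since a group held few counts. LIN7A and TPPP3 had 0 counts in untreated H1650, and the edgeR adjusted p of their difference was 4.28e-04 and 0.00361.

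Among gene lists called by camera at the preset correlation, median differences were more positive in H1650 for nonsense-mediated decay factors (-0.20), DNA replication and E2F targets (-0.23), pro-apoptotic regulators (-0.37), anti-apoptotic regulators (-0.42), antigen presentation (-0.55), NF-kB and cytokine response (-1.10), endoplasmic reticulum chaperones (-0.21), MAPK feedback (-0.74), immediate-early genes (-0.95), Wnt targets (-0.80), replication-dependent histones (-1.23) and proteasome (-0.18), and more positive in A549 for G2/M and mitosis (0.21) and cholesterol synthesis (0.26). With an estimated correlation 1 of the 14 lists kept the call, NF-kB and cytokine response (camera adjusted p = 0.0405), against for example 0.404 for decay factors and 0.566 for proteasome. With 1 member near 0 left out, the cholesterol synthesis median was 0.263.

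Interferon response genes rose in A549 SRSF2 libraries, and untreated H1650 expresses these genes at a far higher level, so RNA carried over from H1650 may have raised them. H1650 marker genes, at 100 or more CPM in untreated H1650 and under 1 CPM in untreated A549, and outside the interferon and antigen presentation lists (12 genes) rose by a median of 0.00615% of their H1650 level, with a highest value of 0.522% for GBP1, itself an interferon-inducible gene, against a median of 5.31% for the interferon genes. This argues against carry-over, and 31 of 34 interferon genes rose above the highest marker, although ENSG00000117289, at 25.8 CPM in untreated H1650 by plain totals and so not among these markers, went from 0.0724 to 2.41 CPM in A549. Library scaling is argued against as well, since the lowest median of the list over 3 other scalings was 1.55 on the log2 scale. Delivery of the construct rather than SRSF2 itself cannot be told apart from an effect of SRSF2, because 0 libraries are described as given an empty construct, and it is not stated what the letters NC in the titles of the untreated libraries stand for.

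Changes were larger in H1650 than in A549, and the interquartile range of log2 fold changes among 9698 genes at 10 CPM or more was 0.586 in H1650 and 0.248 in A549. A larger spread between replicates in H1650, where the common biological coefficient of variation was 0.0459 against 0.0320 in A549, would widen this range, but alone gave a range of 0.0990 in H1650 and 0.0820 in A549. The ratio with it removed was 2.47, which argues against spread between these libraries as the cause. Gene length was taken from the FPKM values, for most genes the genomic span with introns. In this sense it is argued against, since the Spearman correlation of the H1650 log2 fold change with length across genes was -0.0460. The ratio of ranges was at least 1.96 in every length class. Transcript length was not tested and stays open. A difference in the level of SRSF2 reached in the lines was not tested and stays open, as does a biological difference between the lines.

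Genes near 0 in untreated H1650 were called higher more often than lower in H1650 SRSF2 libraries: of 936 genes under 0.2 CPM in every untreated H1650 library, 196 were called higher and 6 lower. Since genes near 0 can hardly be called lower, part of this imbalance follows from the choice of genes. The 4 genes that reached 1 CPM, among them RGS9 and ABCC8, which were chosen after their values were seen, rose by a median of 365% of their A549 level, against a median of 0.0283% for A549 marker genes. This argues against carry-over of A549 RNA for these genes, since 3 of the 4 ended above their level in either A549 group, and ABCC8 rose by 21.4% against at most 1.18% for a marker. The 192 genes that stayed under 1 CPM rose by a median of 15.8% and lie near the floor, so that carry-over of A549 RNA cannot be told apart from a true rise for them.

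Other splits of the same libraries were counted with the same model. For genes whose change differs between the lines, 1 of 100 splits (the real one) gave as many as 7601, and the highest other split gave 6901. That split kept the true H1650 groups and mixed the A549 libraries. Most of the count is thus reached with the true H1650 groups alone, so it does not exclude chance for the A549 groups. The highest split that mixed both lines gave 0. For genes changed in both lines, 1 of 100 splits gave as many as 2898, with 0 in the highest other. A split that mixes SRSF2 and untreated libraries of a line adds the treatment effect to the spread within its groups, which lowers the calls. Counts of 0 in such splits therefore do not exclude chance. For lists whose change differs between the lines, 46 of 100 splits, the real one included, gave as many as 14, and the highest gave 21. A mixed split of a line always leaves more SRSF2 libraries in one group, so part of the treatment effect stays in list counts. In some splits the H1650 labels were also swapped, which turns the difference into a sum of the changes. These list counts therefore neither exclude chance nor measure what chance gives. Within a line, and for the untreated lines, there are only 10 splits, too few for a share under 0.05. The real split, 1 of them, gave 5162 genes in A549, 9957 in H1650 and 13182 between untreated lines, and the highest other split gave 0, 0 and 0. For lists, the real split gave 27 in A549 and 21 in H1650, and the highest other split 19 and 14.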

How the results depend on the processing

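No test in this part was chosen after the results were seen. The alternative that leaves SRSF2 out of the library sizes was not run, since its level was not analysed here. With each library left out in turn, the counts of called genes ran from 4188 to 5510 in A549, 9297 to 9977 in H1650, 7149 to 7654 for the difference, 12963 to 13382 for untreated lines and 2430 to 3028 in both lines. Called lists ran from 26 to 28 in A549, 19 to 21 in H1650 and 12 to 15 for the difference. With a replicate block, 5185 genes were called in A549, 9936 in H1650, 7624 for the difference and 2911 in both lines.

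Other scalings, filters and tools on counts gave counts within 1.5 times those reported, except that 38 genes rather than 60 fell by 1 or more on the log2 scale in A549 with the stricter filter. With DESeq2, 4995 genes were called in A549, of which 4687 were the same genes, and 9623 in H1650, of which 9561 were the same (1288 genes had no adjusted p in A549). Of called genes, 50.8% were higher in A549, 49.8% in H1650 and 50.6% more positive in A549 in the difference. Total-count scaling moved the share to 40.9% in H1650 and to 60.1% in the difference. In A549 the share was 43.7% with RLE scaling and 44.1% with DESeq2.

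On filtered log2(FPKM + 1) with limma-trend, 7402 genes were tested and fewer were called: 3117 in A549 (1336 higher), 5432 (2270 higher and 3162 lower) in H1650, 4561 (2491 higher and 2070 lower) for the difference, 6542 (3249 higher and 3293 lower) for untreated lines and 1899 in both lines. On log2(FPKM + 0.1) the counts were 3137 (1367 higher), 5443 (2271 higher and 3172 lower), 4456 (2473 higher and 1983 lower) and 6538 (3250 higher and 3288 lower). Genes higher and lower by 1 or more on the log2 scale changed from 280 and 60 to 17 and 0 on log2(FPKM + 1) and 63 and 5 on log2(FPKM + 0.1) in A549, and from 1163 and 535 to 192 and 31 on log2(FPKM + 1) and 345 and 143 on log2(FPKM + 0.1) in H1650. For the difference they changed from 594 and 886 to 39 and 157 on log2(FPKM + 1) and 134 and 277 on log2(FPKM + 0.1), and for untreated lines from 2994 and 3299 to 695 and 607 on log2(FPKM + 1) and 1219 and 1037 on log2(FPKM + 0.1). Without a filter these were, on log2(FPKM + 1), 17 and 0 in A549, 193 and 31 in H1650, 39 and 157 for the difference and 696 and 607 for untreated lines. In all, 4780 and 9332 genes were called without a filter in A549 and H1650. The difference for IFI44L reversed to -0.319 on log2(FPKM + 1), with and without a filter, and to -0.014 on log2(FPKM + 0.1), because the offset outweighs its values in A549.

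With an estimated correlation camera called 11 lists in A549, 8 in H1650 and 1 for the difference. fry, which compares no list with other genes, called 31, 34 and 28.

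Of values for single named genes, 21 lost and 3 gained a call under an alternative, 3 reversed and 2658 stayed. With 1 library left out, 18 lost and 2 gained a call. The losses include SRPK2 in A549 without A549 untreated replicate 1 (0.0709), A549 untreated replicate 3 (0.0615) and A549 SRSF2 replicate 1 (0.0907), with the edgeR adjusted p in parentheses. Of list values, 62 lost and 33 gained a call under an alternative, of which 42 losses came with an estimated correlation and 31 gains with fry. The camera adjusted p of the other losses and gains is in parentheses. Splicing kinases in H1650 lost it with total counts (0.0618), the stricter filter (0.0582) and each line fitted alone (0.0578). YAP/TEAD targets in H1650 lost it with total counts (0.0569). Proteasome in H1650 lost it with RLE scaling (0.0538), upper-quartile scaling (0.0599), total counts (0.137), no filter (0.0527), the stricter filter (0.0658), a replicate block (0.0658) and each line fitted alone (0.0654). Long noncoding RNAs in H1650 lost it with the stricter filter (0.0658) and each line fitted alone (0.0539). Nonsense-mediated decay factors for the difference lost it with upper-quartile scaling (0.0601), total counts (0.0978), no filter (0.0517), the stricter filter (0.0710) and a replicate block (0.0547). Anti-apoptotic regulators for the difference lost it with upper-quartile scaling (0.0537) and total counts (0.0594). Nuclear-encoded oxidative phosphorylation in A549 gained it with RLE scaling (0.0470). Cytosolic ribosomal proteins for the difference gained it with total counts (0.0119). Among list values with 1 library left out, 25 lost and 7 gained a call. By camera adjusted p, the call ended for pro-apoptotic regulators in A549 without A549 SRSF2 replicate 2 (0.0613), splicing kinases in H1650 without H1650 untreated replicate 3 (0.0606) and H1650 SRSF2 replicate 1 (0.0609), YAP/TEAD targets in H1650 without H1650 SRSF2 replicate 1 (0.0590) and long noncoding RNAs in H1650 without H1650 untreated replicate 3 (0.0570). It ended for the proteasome in H1650 without A549 untreated replicate 1 (0.0519), A549 untreated replicate 2 (0.0543), A549 untreated replicate 3 (0.0545), A549 SRSF2 replicate 2 (0.0547), H1650 untreated replicate 1 (0.0624), H1650 untreated replicate 2 (0.0514), H1650 SRSF2 replicate 2 (0.0736) and H1650 SRSF2 replicate 3 (0.0668). The difference ended for decay factors without A549 untreated replicate 1 (0.0568), A549 untreated replicate 2 (0.0627), A549 SRSF2 replicate 1 (0.0601), A549 SRSF2 replicate 3 (0.0508), H1650 untreated replicate 1 (0.0518), H1650 untreated replicate 3 (0.0513) and H1650 SRSF2 replicate 1 (0.0855), and for anti-apoptotic regulators without A549 untreated replicate 1 (0.0530), A549 SRSF2 replicate 3 (0.0587), H1650 untreated replicate 1 (0.0651), H1650 untreated replicate 3 (0.0513) and H1650 SRSF2 replicate 3 (0.0655). The cause of these losses was not tested.

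Depth limits statements about genes near 3 counts per library (0.0935 to 0.126 CPM).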

Other observations

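The tests in this part were planned, and the genes named come from the rule given with the methods. Several gene lists changed that belong in no comparison above. Transcripts that host small nucleolar RNAs and are degraded by nonsense-mediated decay rose in both lines. In A549, 9 of 12 genes rose and 0 fell (the same counts adjusted over the list alone, camera adjusted p = 5.92e-06, or adjusted p = 0.148 with an estimated correlation), and in H1650, 10 of 12 genes rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.00614, or adjusted p = 0.360 with an estimated correlation). GAS5 rose from 92.6 ± 1.40 to 144 ± 9.76 CPM in A549, SNHG1 from 80.7 ± 3.60 to 156 ± 12.5 CPM and SNHG15 from 46.8 ± 1.82 to 88.1 ± 0.575 CPM in H1650, and ZFAS1, which lies antisense to its neighbour and can share reads with it, from 121 ± 1.88 to 171 ± 10.2 CPM in A549. Among the factors of the decay pathway, 10 of 17 genes rose and 3 fell (the same counts adjusted over the list alone) in H1650, including UPF3B (1.60) and PNRC2 (0.88) (camera adjusted p = 0.0199, or adjusted p = 0.197 with an estimated correlation). In A549 the camera adjusted p of these factors was 0.313, with a median difference of -0.20 between lines (camera adjusted p = 0.0492, or adjusted p = 0.404 with an estimated correlation). The call for this difference was lost with upper-quartile and total-count scaling, with either other filter and with a replicate block.

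Kinases that phosphorylate SR proteins were called higher as a list by camera at the preset correlation, but not with an estimated one. The H1650 call was also lost under several alternatives, and 62.3% of all genes tested were called in H1650. In A549, 5 of 9 kinase genes rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0101, or adjusted p = 0.202 with an estimated correlation), and in H1650, 5 of 9 kinase genes rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0426, or adjusted p = 0.308 with an estimated correlation). CLK1 had log2 fold changes of 0.66, SE 0.06 in A549 and 1.27, SE 0.05 in H1650, and SRPK2 of 0.14, SE 0.05 and 0.86, SE 0.04. Among nuclear-retained long noncoding RNAs, 4 of 9 transcripts rose and 2 fell (the same counts adjusted over the list alone) in A549 (camera adjusted p = 0.00827, or adjusted p = 0.0610 with an estimated correlation) and 3 of 9 transcripts rose and 2 fell (the same counts adjusted over the list alone) in H1650 (camera adjusted p = 0.0463, or adjusted p = 0.126 with an estimated correlation). PVT1 had log2 fold changes of 0.60 and 0.11, LINC-PINT of 0.83 and 1.95, and NEAT1 of 0.01 and 1.72, in A549 and H1650.

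In the proteasome, 19 of 26 subunit genes rose and 3 fell (the same counts adjusted over the list alone) in H1650, including PSMC4 (0.73) and PSMC1 (0.54) (camera adjusted p = 0.0494, or adjusted p = 0.547 with an estimated correlation), and in A549 the camera adjusted p was 0.183. The H1650 call was lost with every other scaling and filter, and with most single libraries left out. In A549, 6 of 18 integrin and laminin genes rose and 1 fell (the same counts adjusted over the list alone), with ITGA3 (0.46) higher (camera adjusted p = 0.00354, or adjusted p = 0.282 with an estimated correlation), and in H1650 the camera adjusted p was 0.736. In A549, 8 of 21 mesenchymal genes rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.0126, or adjusted p = 0.101 with an estimated correlation), and 8 of 19 angiogenesis factors rose and 3 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0286, or adjusted p = 0.0990 with an estimated correlation), with camera adjusted p = 0.134 and 0.391 in H1650. For cytosolic ribosomal protein genes in A549, 31 of 72 genes rose and 0 fell (36 and 0 adjusted over the list alone, camera adjusted p = 8.59e-04, or adjusted p = 0.619 with an estimated correlation), with a median of 0.09, and the camera adjusted p in H1650 was 0.766.

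Lists described above for the other line gave these values. In A549, 8 of 24 pro-apoptotic genes rose and 4 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0332, or adjusted p = 0.0990 with an estimated correlation) and 7 of 10 anti-apoptotic genes rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 1.64e-04, or adjusted p = 0.0578 with an estimated correlation). In H1650, 12 of 22 YAP/TEAD targets rose and 5 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0261, or adjusted p = 0.471 with an estimated correlation). Other lists were not called in H1650, with camera adjusted p = 0.652 for cholesterol synthesis, 0.250 for the heat shock response and 0.132 for drug metabolism.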
